A study of Homo sapiens with 4 samples.

How the data were processed

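The series holds 4 RNA-seq libraries of HT-1080 cells, of which 2 carry a control guide, 1 a guide against protein kinase A and 1 a guide against ALKBH5, per the labels' genotype field. RNA was enriched for messenger RNA with capture beads, per the labels' protocols. The submitters' processing notes name fastp 0.18.0, HISAT2 2.1.0, StringTie 1.3.1, RSEM and the build GRCh38.p14, with no statement of which tool made the values, and the annotation release is not given in the sources used here. The authors deposited 1 table with expected counts and TPM per gene and library. The expected counts are not normalised, per the file headers and the values, of which between 10.6% and 12.7% per library are not whole numbers. The deposited TPM values sum to the same total in each library. Strand use in counting is not given in the sources used here, so antisense and overlapping genes cannot be told apart. Of 20323 genes, 3989 had no counts in any library, and 488 rows repeat a gene symbol, for which the row with the highest mean TPM was used.

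Expected counts were rounded and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. All 4 libraries entered 1 fit with 3 groups. The spread came from the 2 controls alone, with 1 residual degree of freedom per gene, and each lone knockout library was assumed to vary like the controls. A call therefore compares these libraries and not the genotypes beyond them. Total counts ran from 14050867 in sgPKA to 25937347 in sgALKBH5, so 3 counts correspond to 0.201 and 0.118 CPM after normalization in these libraries. The filter left 13061 genes. The biological coefficient of variation was 0.347 and the prior degrees of freedom were 3.15. A rule without a test counted genes whose log2(TPM + 1) differed by at least 1 in the same direction from both controls, among 11629 genes with a mean TPM of at least 1. Folds on this scale understate changes of low genes.

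The script was tested on simulated data for sgPKA against control over 13061 genes, with 100 genes changed 4-fold and 100 changed 16-fold. With the trended dispersion in every gene, edgeR recovered 66% and 95% of them. With a dispersion that varied between genes as estimated from the controls, it recovered 0% and 0%, while DESeq2 1.42.0 recovered 51% and 94% and called 197 unchanged genes. The 2-fold rule then recovered 83% and 100% and passed 864 unchanged genes. On log2(CPM + 1), limma recovered 4% and 66% with the trended dispersion and 0% and 0% with the varying one.

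There were 25 gene lists, fixed before the data were examined. For each, the median log2 difference of TMM-normalised counts was computed for the measured members, with its percentile among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile describes these libraries and is not a test across replicates. The same was computed for control 2 against control 1. There too, several lists lay outside the middle 95%, such as cholesterol synthesis at percentile 99.94 and ATF4 targets at 0.03. The extracellular matrix list lay inside, at 33.5, with quartiles of -1.29 and 0.395 around its median. Such a percentile thus also arises between libraries with a control guide and is no sign of a knockout effect by itself. The script was checked on the real sgPKA differences with random lists of 20 genes. All 20 lists shifted by 1 lay above percentile 97.5, and 0 of 20 unshifted lists lay outside the middle 95%. Random lists were there compared with random lists, so the check cannot show how often lists of genes that vary together fall outside.

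Genes were named by a rule fixed in advance. PKA subunit genes, ALKBH5, FTO, METTL3, METTL14 and GPX4 were always named. For each knockout the 10 largest differences each way were taken among genes called and at least 2-fold from both controls, with an official symbol and a TPM of at least 5 in the knockout or the control mean. Because fewer than 5 genes were called, the call was not required. Between the knockouts the 5 largest each way were taken. For each list with fewer than 2 called members, the 2 members with the highest mean TPM were named. Where a knockout had 0 counts, the fold is a bound against a floor of 3 counts per library. Where it had 1 to 3 counts, an exact 95% interval is given. Intervals and floors cover counting error only.

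Alternatives were the size factors of DESeq2, its Wald test, no filter, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), other TPM minimums, TPM rescaled by TMM factors, only the 3 libraries compared, and each control left out. Shared controls were treated by simulating 100 pairs of unchanged knockout libraries against the real controls, with negative binomial counts. GC content and length came from the GENCODE transcripts, and positions from the RefSeq annotation of GRCh38.p14, joined by symbol. For the gene lists, PRKACA, ALKBH5 and GPX4, the median of genes matched on GC content and length was also subtracted. Of the genes compared, 99.8% had a GC content and length. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.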

Results

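RNA-seq libraries were made from polyadenylated RNA of HT-1080 cells, a human fibrosarcoma line used widely in work on ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. There were 2 libraries of cells with a control guide RNA (control 1 and control 2), 1 library of cells with a guide against protein kinase A (sgPKA) and 1 library of cells with a guide against ALKBH5 (sgALKBH5), a demethylase of N6-methyladenosine (m6A) in RNA. The series title ties both genes to ferroptosis and to m6A on the transcript of GPX4, the enzyme that reduces lipid hydroperoxides. The table held 20323 genes. Total counts were 18469299 in control 1, 18522402 in control 2, 14050867 in sgPKA and 25937347 in sgALKBH5. Each knockout had 1 library, so no difference between a knockout and the controls has a replicate check. The labels do not say that the controls were separate cultures, so how much of the spread between them is technical is not known. Counting error alone is argued against. At like total counts, 9 genes at 10 TPM or more in control 1 had at most 3 counts in control 2, and 0 genes the other way.

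The 4 libraries did not group by genotype. The standard deviation over 11629 genes of the difference in log2(TPM + 1) was 0.585 between the 2 controls. It was 0.390 between control 1 and sgALKBH5 and 0.547 between control 2 and sgPKA, both smaller than between the controls. It was 0.738 between control 1 and sgPKA, 0.668 between control 2 and sgALKBH5 and 0.817 between the knockouts. In all, 745 genes lay at least 2-fold apart between the controls. Values are against the control mean unless a single control is named.

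**Figure D1:**
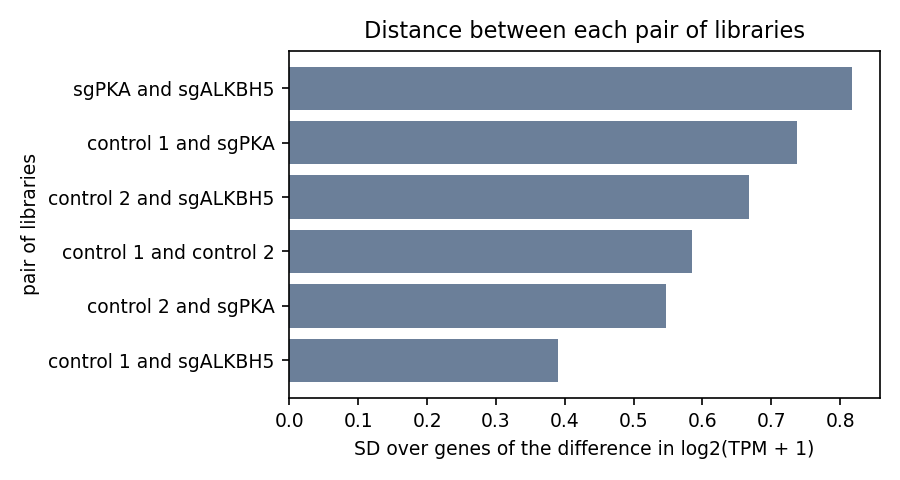
Standard deviation over genes of the difference in log2(TPM + 1) for each pair of the 4 libraries, 1 bar per pair. The pair of control 1 and sgALKBH5 has the smallest value, 0.390, and the pair of control 2 and sgPKA, at 0.547, also lies below the pair of controls, at 0.585.

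The comparison of sgPKA with the controls asks what loss of protein kinase A does to the transcriptome. PRKACA, which encodes the catalytic subunit alpha of the kinase, stood at 10.6 TPM in sgPKA against 65.3 ± 6.76 TPM in the controls (SD, n = 2) and 70.9 TPM in sgALKBH5. The labels do not say which subunit gene the guide targeted. In GRCh38.p14 PRKACA (ENSG00000072062) lies on chromosome 19 from 14091688 to 14117762. Its count-based log2 fold change was -2.77 with a standard error of 0.29, and the difference in log2(TPM + 1) was -2.51. Transcripts of the catalytic subunit beta gene PRKACB were at 3.47 and 6.79 TPM in the controls and 7.28 TPM in sgPKA, and PRKACG had no counts in any library. The regulatory subunit gene PRKAR1A was at 96.3 and 86.0 TPM in the controls and 165 TPM in sgPKA. PRKAR1B was at 19.9 and 17.6 TPM in the controls and 36.6 TPM in sgPKA, PRKAR2A at 39.3 and 40.9 against 55.0 TPM, and PRKAR2B at 5.65 and 6.42 against 9.73 TPM. The count-based log2 fold change of PRKAR2A was only 0.05, and that of PRKAR1A was 0.77.

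GPX4 (ENSG00000167468, chromosome 19 from 1103994 to 1106779) was at 269 TPM in sgPKA against 441 ± 32.0 TPM in the controls (SD, n = 2). On the scale of log2(TPM + 1) the difference was -0.71. The count-based log2 fold change was larger, at -0.91 with a standard error of 0.24. The 200 genes closest to GPX4 in GC content and transcript length had a median log2 difference of -0.47 in this library. Among the m6A genes, ALKBH5 was at 80.2 and 67.6 TPM in the controls and 67.1 TPM in sgPKA. FTO, the other m6A demethylase, was at 41.6 and 33.0 TPM in the controls and 43.5 TPM in sgPKA. The methyltransferase genes METTL3 and METTL14 were at 78.1 and 4.58 TPM in sgPKA, against 70.7 and 71.8 TPM for METTL3 and 2.24 and 5.26 TPM for METTL14 in the controls. The count-based log2 fold changes were -0.325 for ALKBH5, -0.059 for FTO, -0.051 for METTL3 and 0.219 for METTL14. The higher TPM of FTO and METTL3 was thus not seen in normalised counts.

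**Figure D2:**
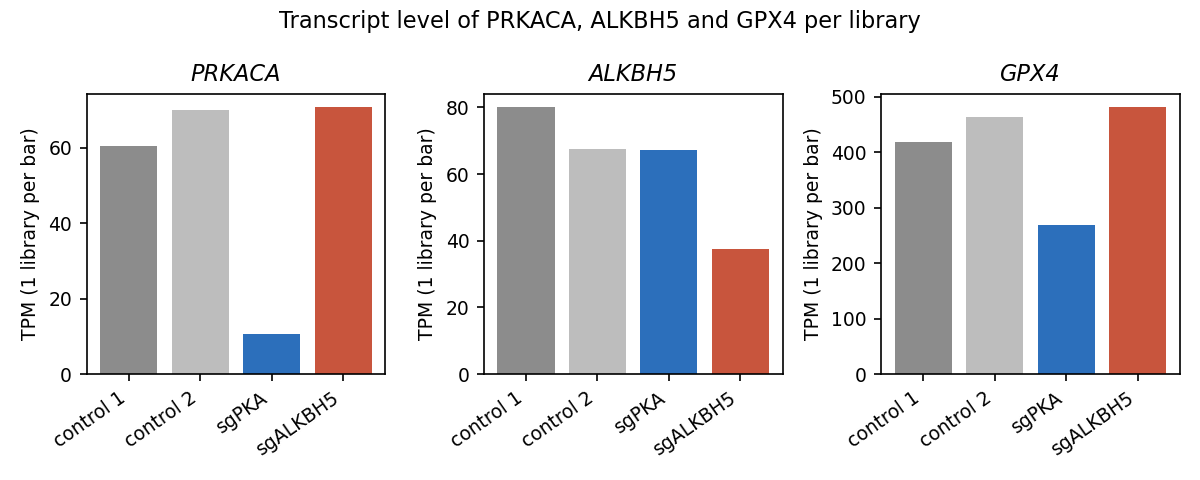
TPM of PRKACA, ALKBH5 and GPX4 in each of the 4 libraries, 1 bar per library. PRKACA is lowest in sgPKA at 10.6 TPM, ALKBH5 is lowest in sgALKBH5 at 37.5 TPM, and GPX4 is lowest in sgPKA at 269 TPM.

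Genes of cholesterol and fatty acid synthesis were higher in sgPKA. The median log2 difference of the 26 measured members from the control mean was 0.55, above 100% of 10000 random lists matched on expression, and 20 members lay above both controls. The 2 members with the highest mean TPM are the fatty acid desaturase gene SCD, at 443 TPM against 210 ± 7.89 TPM (SD, n = 2), and the citrate lyase gene ACLY, at 265 TPM against 204 ± 3.07 TPM. HMGCS1, an early enzyme of the mevalonate pathway, was at 91.7 TPM in sgPKA against 24.6 and 27.8 TPM in the controls. The median was 0.72 against control 1 alone and 0.33 against control 2 alone. Control 2 itself lay above control 1 by 0.25, at percentile 99.94. List members named in addition to the 2 with the highest mean TPM were chosen here and below after their values were seen, for lying at least 2-fold from both controls.

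Target genes of ATF4, the transcription factor of the integrated stress response, were also higher in sgPKA. The median of their 26 measured members was 0.525, above 100% of random lists, and -0.26 for control 2 against control 1. ATF4 was at 900 TPM against 683 and 449 TPM in the controls, while GDF15 was at 1123 TPM against 1586 and 1692 TPM. The asparagine synthetase gene ASNS was at 253 TPM against 116 and 101 TPM. SLC7A11, the cystine transporter subunit that supplies glutathione synthesis, was at 11.03 TPM against 4.19 and 3.10 TPM. When p-values of edgeR were adjusted over the list alone, 4 members passed, and over all genes 0 passed.

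The ferroptosis defence list had a median of 0.23 over 24 members in sgPKA, at percentile 98.1, and the NRF2 target list one of 0.22 over 24, at percentile 98.3. Less genes matched on GC content and transcript length, the ferroptosis defence median was 0.11 and the NRF2 median 0.30. Against control 1 and control 2 alone the NRF2 median was 0.37 and 0.14, the latter at percentile 91.2, inside the middle 95% of random lists. The ferritin genes FTH1 and FTL lead both lists and the iron handling list in level. FTH1 was at 6557 TPM in sgPKA against 4012 and 4413 TPM, and FTL at 6148 TPM against 3800 and 6142 TPM. The haem oxygenase gene HMOX1 was at 196 TPM against 42.0 and 52.4 TPM. The p53 target list had a median of 0.22 over 23 members, at percentile 99.2. It was 0.41 against control 1 alone and 0.10 against control 2 alone, the latter at percentile 88.2, inside the middle 95%. Less genes matched on GC content and length, the median of this list was 0.345. CDKN1A, its member with the second highest mean TPM after GDF15, was at 472 TPM against 406 and 511 TPM. TP53INP1 was at 13.1 TPM against 2.68 and 3.33 TPM.

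Hypoxia and glycolysis genes were lower in sgPKA, with a median of -0.79 over 24 members, below all of the random lists, and 19 members lay below both controls. ENO1 was at 4323 TPM against 5434 and 5901 TPM, and GAPDH at 12940 TPM against 15710 and 14790 TPM. The carbonic anhydrase gene CA9 was at 1.22 TPM against 89.9 and 17.7 TPM. Adjusted over the list alone, 8 members passed in edgeR, and over all genes 0 passed. The median of control 2 against control 1 was -0.37, also below all of the random lists.

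Extracellular matrix and mesenchymal genes had a median of -0.78 over 30 members in sgPKA, below all random lists. It was -0.91 against control 1 and -0.53 against control 2 alone. Control 2 against control 1 gave -0.02, but with quartiles of -1.29 and 0.395, so members also differed between the controls, in both directions. The matrix protein gene SPARC was at 635 TPM against 2215 and 909 TPM, and VIM at 7839 TPM against 6730 and 6840 TPM. The gelatinase gene MMP9 was at 14.8 TPM against 111 and 127 TPM. The epithelial markers KRT8 and KRT18 were at 209 and 269 TPM in sgPKA. In control 1 and control 2 KRT8 was at 686 and 546 TPM, and KRT18 at 706 and 477 TPM. This list had a median of -1.82 over 6 measured members. Target genes of cAMP and CREB had a median of -0.51 over 21 members, at percentile 0.1, with -0.60 for control 2 against control 1. It was -0.70 against control 1 alone and -0.18 against control 2 alone, the latter at percentile 7.07, inside the middle 95%. JUNB was at 52.8 TPM against 96.4 and 59.5 TPM, and CREM at 49.7 TPM against 35.6 and 40.5 TPM. The immediate early gene EGR1 was at 3.90 TPM against 24.5 and 12.05 TPM.

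Among single genes at least 2-fold above both controls, the 10 with the largest log2 fold changes were NUPR1, LAIR2, PINLYP, KRCC1, TP53INP1, HMOX1, PLA2G4C, PCDHGC5, TMEM154 and HDAC9, from 1.70 to 3.77. The stress-induced gene NUPR1 was at 25.2 TPM against 0.942 and 2.08 TPM. PCDHGC5 shares exons with the other genes of its protocadherin cluster, so its counts are uncertain. The 10 largest differences in the other direction were genes with 0 counts in sgPKA, namely PLPPR2, PHKA1, CD9, ANXA3, TRBC2, TP53I11, BEX1, IGFBP2, IAH1 and BDH1. Against a floor of 3 counts in the sgPKA library, or 0.201 CPM after normalization, they were at least 43.1-fold (BDH1) to at least 87.4-fold (PLPPR2) lower than the control mean. Several were already low in control 2, such as IAH1 at 23.4 and 1.25 TPM in the controls. The tetraspanin gene CD9 was at 33.4 and 10.2 TPM, TP53I11 at 12.5 and 16.1 TPM and BEX1 at 28.1 and 15.6 TPM.

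The quasi-likelihood test of edgeR called 0 of 13061 genes between sgPKA and control at an adjusted p of 0.05. At an unadjusted p under 0.05 it counted 1184 genes, and PRKACA had an adjusted p of 0.527. DESeq2 called 115 genes, 13 higher and 102 lower in sgPKA, and limma called 0. Without a test, 121 genes lay at least 2-fold above both controls and 162 at least 2-fold below both. Against control 2 alone the total of 283 genes became 668, with 401 higher and 267 lower. Against control 1 alone it became 1135, with 467 higher and 668 lower, so the split turned with the control used. TPM values of sgPKA ran above those of the controls by a median of 0.15 on the log2 scale, while the count-based values were centred at -0.01. With TPM rescaled by the count-based factors, the split was 73 higher and 198 lower. Unchanged libraries simulated against the same controls gave a mean of 709 such genes, more than the 283 observed. The simulated libraries thus lay farther from the controls than sgPKA did, and this comparison cannot show an excess of changed genes.

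The comparison of sgALKBH5 with the controls asks what loss of the demethylase does. ALKBH5 (ENSG00000091542, chromosome 17 from 18183828 to 18209954) was at 37.5 TPM in sgALKBH5 against 73.9 ± 8.91 TPM in the controls (SD, n = 2). Its count-based log2 fold change was -1.05 with a standard error of 0.23. GPX4 was at 482 TPM, with a count-based log2 fold change of 0.05 and a standard error of 0.23, which turned to -0.06 against control 2 alone. FTO was at 41.0 TPM, METTL3 at 81.8 TPM and METTL14 at 2.51 TPM. PRKACA was at 70.9 TPM, PRKACB at 3.70 TPM, PRKAR1A at 97.0 TPM, PRKAR2A at 49.1 TPM and PRKAR2B at 4.62 TPM. PRKAR1B was at 8.45 TPM, below both controls, with a log2 fold change of -1.59.

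Interferon response genes were higher in sgALKBH5 than in both controls. The median log2 difference of 24 measured members from the control mean was 1.55, above 100% of random lists, and it was 1.002 against control 1 and 2.05 against control 2. The ubiquitin-like gene ISG15 was at 680 TPM against 205 ± 31.3 TPM (SD, n = 2). The oligoadenylate synthetase-like gene OASL was at 557 TPM against 142 TPM in control 1 and 11.5 TPM in control 2. Of the 24 members, 18 lay above both controls and 2 below both. Control 2 lay below control 1 for this list, with a median of -1.07, itself below all random lists. The median of sgPKA was -0.75 against the control mean, -1.095 against control 1 and -0.23 against control 2, the last with 10 members higher and 14 lower and at percentile 2.54, just inside the middle 95% of random lists. Adjusted over the list alone, 2 members passed in edgeR, and over all genes 0 passed.

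The NF-kB and inflammatory cytokine list had a median of 1.44 over 20 members in sgALKBH5, above 100% of random lists, and 19 members lay above both controls. Control 2 against control 1 gave -1.54, below all random lists. The chemokine gene CCL5 was at 408 TPM against 153 and 43.1 TPM in the controls. IL1B was at 933 TPM against 432 and 708 TPM, and at 1331 TPM in sgPKA. The NF-kB inhibitor gene NFKBIA was at 102 TPM against 47.5 and 27.0 TPM. In sgPKA the direction of the list turned with the control used, with a median of -1.105 against control 1 and 0.40 against control 2. Against the control mean it was -0.13, and -0.72 with low counts set to the floor of 3.

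Genes of cholesterol and fatty acid synthesis were lower in sgALKBH5, with a median of -0.67, below all random lists, with -0.51 against control 1 and -0.94 against control 2, and 22 of 26 members lay below both controls. SCD was at 148 TPM and ACLY at 212 TPM. FADS2, the delta-6 desaturase gene, was at 16.3 TPM against 177 and 180 TPM, and HMGCS1 at 11.1 TPM against 24.6 and 27.8 TPM. The p53 target list had a median of -0.34, below all random lists, with -0.14 against control 1 and -0.54 against control 2. Less genes matched on GC content and length, it was -0.23. GDF15, also on the ATF4 list, was at 374 TPM against 1586 and 1692 TPM, and CDKN1A at 349 TPM. Hypoxia and glycolysis genes had a median of 0.49, at the top of the random lists, and 18 of 24 lay above both controls. ENO1 was at 6093 TPM and GAPDH at 16180 TPM. The median against control 1 alone was 0.19. Extracellular matrix genes had a median of 0.38, which was 0.14 against control 1 alone. SPARC was at 1742 TPM and VIM at 7853 TPM, while MMP9 was at 453 TPM against 111 and 127 TPM. In the other direction, MMP3 was at 3.41 TPM against 15.7 and 17.8 TPM. Of this list, 3 members lay at least 2-fold above both controls and 1 at least 2-fold below both. Target genes of cAMP and CREB had a median of 0.39 against the control mean and 0.00 against control 1 alone. JUNB was at 120 TPM and CREM at 31.6 TPM.

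**Figure D3:**
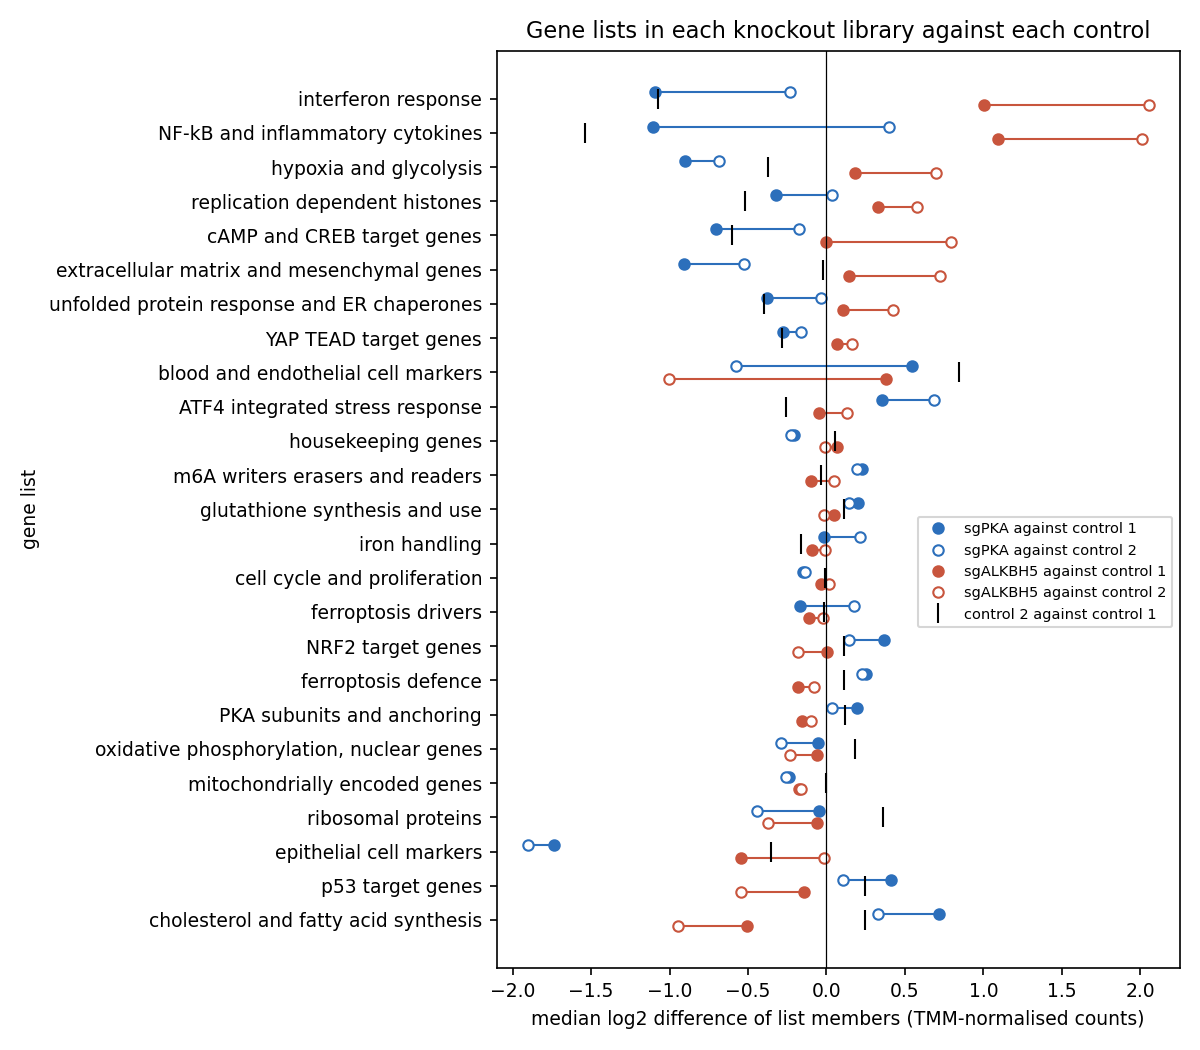
Median log2 difference of the members of each of 25 gene lists in sgPKA and sgALKBH5 against control 1 (filled points) and control 2 (open points), with control 2 against control 1 as a vertical tick. The interferon list lies at 1.002 and 2.05 in sgALKBH5, and the cholesterol list lies above 0 in sgPKA and below 0 in sgALKBH5 against either control.

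**Figure D4:**
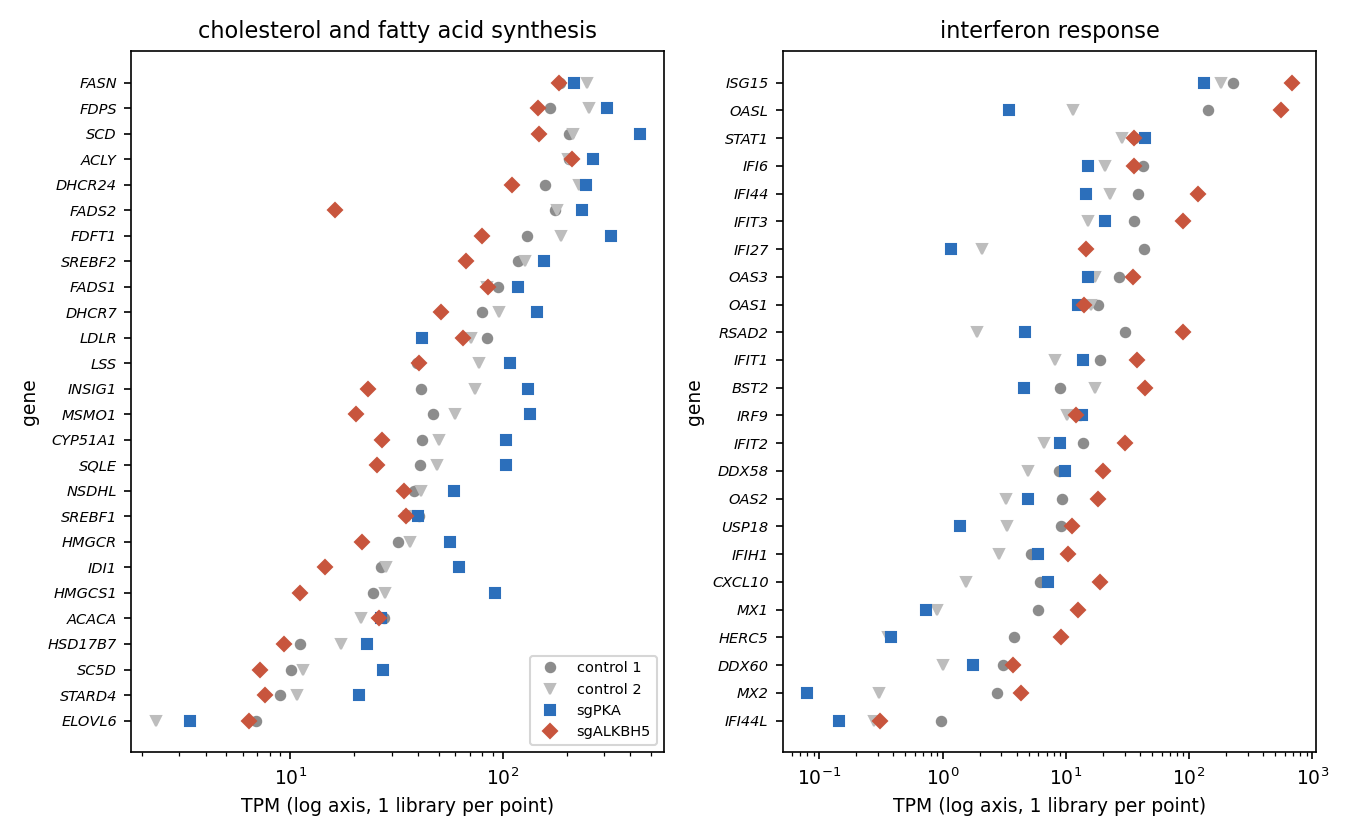
TPM of each measured member of the cholesterol and fatty acid synthesis list and of the interferon list in the 4 libraries, on a log axis, 1 point per library. HMGCS1 ranges from 11.1 TPM in sgALKBH5 to 91.7 TPM in sgPKA, and OASL from 3.43 TPM in sgPKA to 557 TPM in sgALKBH5.

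Among single genes at least 2-fold above both controls in sgALKBH5, the 10 largest log2 fold changes, from 3.12 to 5.86, included those of BMP7, SSX2, SSX2B, FNDC10, ICAM1, OLFM2, TMEM255B, CCL3L1 and GABBR2. BMP7, a secreted growth factor of the TGF-beta family, was at 23.5 TPM against 0.704 and 0 TPM, and the adhesion molecule gene ICAM1 at 31.4 TPM against 4.09 and 0.172 TPM. SSX2 and SSX2B carried identical values and CCL3L1 has near-identical copies, so these levels are uncertain per gene. The 10 largest in the other direction were TM4SF19-DYNLT2B, ACP7, CSPG4, SLC43A3, ACTL8, TMEM42, IL24, FABP5, SMIM11 and ZNF185. SLC43A3, a solute carrier gene, was at 4.86 TPM against 130 and 232 TPM, and the fatty acid-binding protein gene FABP5 at 1.14 TPM against 32.3 and 23.6 TPM. TM4SF19-DYNLT2B, a readthrough locus that overlaps its component genes, had 0 counts and was at least 36.3-fold lower. ACP7 had 2 counts, a ratio of 169 with an exact 95% counting interval from 46.4 to 1400, and TMEM42 had 2 counts, a ratio of 40.1 with an interval from 10.9 to 335. ACTL8 and IL24 were at 16.8 and 13.9 TPM in control 1 but at 479 and 333 TPM in control 2. SMIM11 was at 0.401 TPM in sgPKA and 0.460 TPM in sgALKBH5 against 17.2 and 22.98 TPM, while its near-identical copy SMIM11B was at 34.4 and 33.5 TPM against 15.4 and 15.1 TPM. The sum of both was between 32.6 and 38.1 TPM in every library, so the single values are uncertain.

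For sgALKBH5 against control, edgeR called 0 of 13061 genes, with 369 at an unadjusted p under 0.05, and the adjusted p of ALKBH5 was 0.998. DESeq2 called 40 genes, 15 higher and 25 lower, and limma called 0. In all, 120 genes lay at least 2-fold above both controls and 56 at least 2-fold below both. The total of 176 became 974 against control 2 alone and 301 against control 1 alone. The simulated mean for an unchanged library was 699, again more than observed.

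The remaining lists are given for sgPKA and then sgALKBH5 against the control mean. The PKA subunit and anchoring list had medians of 0.12 and -0.13. In sgPKA it was 0.19 against control 1 and 0.03 against control 2, and turned to -0.09 less genes matched on GC content and length. The m6A writer, eraser and reader list had medians of 0.22 and 0.00. In sgPKA the genes matched on GC content and length had a median of 0.22 as well, and the list less these genes gave 0.04. HNRNPC was at 869 and 833 TPM in the controls, 896 TPM in sgPKA and 861 TPM in sgALKBH5, and HNRNPA2B1 at 281 and 286 TPM, then 340 and 292 TPM. Ferroptosis defence and NRF2 targets were both at -0.10 in sgALKBH5. Against control 1 and control 2 in turn, ferroptosis defence was at -0.18 and -0.08 and NRF2 targets at 0.01 and -0.18. In this library FTH1 was at 3504 TPM and FTL at 3391 TPM. Ferroptosis drivers had medians of -0.03 and -0.03, with -0.17 and 0.18 in sgPKA against control 1 and control 2 and 0.14 less matched genes. In sgALKBH5 the median was -0.11 against control 1 and -0.02 against control 2. TFRC, the transferrin receptor gene, was at 233 and 166 TPM, then 316 and 267 TPM, and VDAC2 at 345 and 324 TPM, then 298 and 346 TPM. Glutathione genes had medians of 0.20 and -0.02, with 0.09 in sgPKA less matched genes. In sgALKBH5 this turned with the control used, with 0.05 against control 1 and -0.02 against control 2. GPX1 was at 656 and 1240 TPM, then 1027 and 815 TPM, and GSTP1 at 625 and 658 TPM, then 557 and 528 TPM. Iron handling genes had medians of 0.16 and -0.02. In sgPKA this turned with the control used, with -0.01 against control 1 and 0.21 against control 2, and was 0.04 less genes matched on GC content and length. ATF4 targets stood at 0.075 in sgALKBH5, with -0.045 against control 1 and 0.13 against control 2, and ATF4 was at 525 TPM.

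Genes of the unfolded protein response had medians of -0.26 and 0.25, with HSPA5 at 706 and 438 TPM in the controls, 476 TPM in sgPKA and 784 TPM in sgALKBH5, and CALR at 1794 and 1430 TPM, then 1216 and 2013 TPM. Against control 1 and control 2 in turn, the medians were -0.38 and -0.04 in sgPKA and 0.10 and 0.43 in sgALKBH5. Control 2 against control 1 gave -0.40, and sgALKBH5 against the mean lay at percentile 99.98. Cell cycle genes had medians of -0.13 and -0.03, with -0.23 in sgPKA less matched genes. In sgALKBH5 the median was -0.04 against control 1 and 0.01 against control 2. CDC20 was at 318 and 469 TPM, then 280 and 373 TPM, and MCM7 at 412 and 420 TPM, then 373 and 401 TPM. YAP and TEAD targets had medians of -0.26 and 0.11. In sgPKA the median was -0.28 against control 1, -0.16 against control 2 and -0.09 less matched genes. CCN1 was at 563 and 676 TPM, then 285 and 626 TPM, and AXL at 478 and 628 TPM, then 521 and 546 TPM. Ribosomal protein genes had medians of -0.24 and -0.22, against 0.36 for control 2 over control 1. The medians were -0.05 and -0.06 against control 1 and -0.45 and -0.37 against control 2. Less genes matched on GC content and length they were -0.04 and -0.18, and in sgPKA the matched genes themselves had -0.22. RPLP0 was at 5984 and 6977 TPM, then 5614 and 5534 TPM, and RPS2 at 8840 and 11000 TPM, then 9187 and 7842 TPM. Nuclear genes of oxidative phosphorylation had medians of -0.13 and -0.15, which were -0.06 and -0.06 against control 1 and -0.29 and -0.23 against control 2, with ATP5F1B at 1506 and 1439 TPM, then 1379 and 1348 TPM, and COX4I1 at 697 and 772 TPM, then 733 and 610 TPM. Mitochondrially encoded genes had medians of -0.28 and -0.17, with -0.16 and -0.13 less matched genes, and with MT-CO1 at 15750 and 15320 TPM, then 14640 and 13520 TPM, and MT-CO3 at 15430 and 13010 TPM, then 13240 and 13730 TPM.

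Replication-dependent histone genes, of which 10 were measured, had medians of -0.17 and 0.44. These lay at percentiles 28.2 and 96.8, inside the middle 95% of random lists. In sgPKA the median was -0.32 against control 1 and 0.04 against control 2, and in sgALKBH5 0.33 and 0.58. Less matched genes, the medians were 0.01 and 0.50. Their most abundant members were H1-2, at 138 and 58.5 TPM in the controls, then 59.0 and 130 TPM, and H2BC12, at 94.7 and 83.9 TPM, then 87.4 and 131 TPM. Housekeeping genes had medians of -0.16 and 0.07, with -0.09 in sgPKA less matched genes and -0.01 in sgALKBH5 against control 2, and with ACTB at 7885 and 8377 TPM, then 7422 and 8698 TPM, and RPL13A at 4963 and 5412 TPM, then 4705 and 4898 TPM. Epithelial markers were at -0.33 in sgALKBH5, with -0.55 against control 1 and -0.02 against control 2, and with KRT8 at 395 TPM and KRT18 at 441 TPM. Of 16 blood and endothelial markers, 5 were measured, with medians of -0.15 and 0.09 and of 0.845 for control 2 over control 1. These turned with the control used, with 0.55 and -0.58 in sgPKA and 0.38 and -1.004 in sgALKBH5 against control 1 and control 2. Their 2 most abundant members were CD68, at 258 and 443 TPM, then 354 and 220 TPM, and LYZ, at 0.136 and 1.93 TPM, then 1.46 and 0.834 TPM.

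Set directly against each other, sgPKA and sgALKBH5 were the pair farthest apart. Of 11629 genes, 661 were at least 2-fold higher in sgPKA and 824 at least 2-fold higher in sgALKBH5. The 5 largest differences toward sgPKA were TM4SF19-DYNLT2B and LAIR2, with 0 counts in sgALKBH5 and at least 70.4-fold and 21.6-fold higher in sgPKA, and GJB2, ACP7 and MAGEC2. GJB2, the connexin 26 gene, was at 22.2 TPM in sgPKA and had 1 count in sgALKBH5, a ratio of 635 with an interval from 113 to 25200. It was at 0.177 TPM in control 1 and 18.9 TPM in control 2. ACP7 had 2 counts in sgALKBH5, a ratio of 418 with an interval from 115 to 3460, and MAGEC2 had 3 counts, a ratio of 241 with an interval from 81.8 to 1170. The 5 largest toward sgALKBH5 were TINAGL1, CHST15, TRBC2, COL12A1 and PLPPR2, each with 0 counts in sgPKA. TINAGL1 was at least 844-fold lower in sgPKA, with 143 TPM in sgALKBH5, 52.1 TPM in control 1 and 0.052 TPM in control 2. The collagen gene COL12A1 was at least 276-fold lower, with 13.1 TPM in sgALKBH5, 8.45 TPM in control 1 and 0.791 TPM in control 2. The test of edgeR called 0 of 13061 genes, with 1521 at an unadjusted p under 0.05. DESeq2 called 309 genes, 79 higher and 230 lower in sgPKA, and limma called 0.

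Whether the knockouts shifted the same genes was examined across genes, which are not independent replicates. The log2 differences of the knockouts from the shared control mean correlated at r = -0.22 over 11629 genes, with a covariance of -0.0587. Unchanged libraries simulated against the same controls gave a mean r of 0.12, from 0.0745 to 0.165 in 95% of 100 draws, and a covariance of 0.0497. These simulated libraries spread more than the real ones, as their 2-fold counts above show, so the simulated r is a rough guide only. With separate controls, r was -0.57 for sgPKA against control 1 and sgALKBH5 against control 2, and -0.04 for the crossed assignment. The first sets each knockout against its farther control, so the difference between the controls can enter both sides with opposite signs. The crossed assignment sets each against its nearer control, and little opposition was left there. There were 4 genes at least 2-fold above both controls in both knockouts and 9 below both in both. Those counts include SMIM11B and SMIM11, whose reads cannot be assigned with certainty. Independent lists would share 1.25 and 0.78 genes, and unchanged libraries against these controls shared 14.01 and 127. There were 12 genes lower in sgPKA and higher in sgALKBH5, and 4 genes the other way, where independent lists would share 1.67 and 0.583 and the simulated unchanged libraries shared 39.8 and 37.4. The simulated lists were longer and spread more than the observed ones, so whether the observed overlaps exceed the effect of shared controls stays open.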

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

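For 5 gene lists, sgPKA lay on one side of both controls and sgALKBH5 on the other, each outside the middle 95% of random lists against the control mean. The difference between the knockouts was not tested, since each has 1 library. The medians in sgPKA and sgALKBH5 were 0.546 and -0.671 for cholesterol and fatty acid synthesis. They were 0.221 and -0.343 for p53 target genes, -0.793 and 0.492 for hypoxia and glycolysis, -0.748 and 1.55 for the interferon response, and -0.781 and 0.375 for extracellular matrix and mesenchymal genes. For control 2 against control 1, the interferon, hypoxia, cholesterol and p53 lists gave -1.07, -0.37, 0.25 and 0.25. Each of these lay in the direction of sgPKA against control 1 and outside the middle 95% of random lists. The extracellular matrix list gave -0.02, at percentile 33.5. Its quartiles there were -1.29 and 0.395, so a median near 0 does not mean that its members were alike in the controls. Against control 2 alone the medians in sgPKA were -0.23 for interferon, 0.10 for p53, 0.33 for cholesterol and -0.53 for extracellular matrix genes, and the p53 and interferon values lay inside the middle 95% of random lists, at percentiles 88.2 and 2.54. Against control 1 alone the medians in sgALKBH5 were -0.14 for p53, 0.19 for hypoxia and 0.14 for extracellular matrix genes.

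The interferon and NF-kB list genes were higher in sgALKBH5 than in both controls. These lists also differed between the controls, so sgALKBH5 could have lain farther along that same difference. The 44 members measured lay above control 1 by a median of 1.02 log2 units (95% bootstrap interval 0.581 to 1.21) more than matched genes. Those genes had a like difference between the controls and a like level, which argues against a shift shared by all such genes. A shift along a difference particular to these lists is not excluded, since the matching used only the size of the difference and the level. Bias by GC content or transcript length is also argued against, since the excess over genes matched on these was 1.03 (0.582 to 1.19). Both intervals rest on 1 sgALKBH5 library and 1 control library, so they hold no spread between libraries. Loss of ALKBH5, or a difference between the cultures unrelated to the guide, both stay open, and 1 library cannot separate them.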

How the results depend on the processing

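No paired analysis was possible because each knockout has 1 library and the labels pair none of them with a control. The rule that also asks for a gene to lie farther from the nearer control than the controls lie from each other, and the alternatives that subtract genes matched on GC content and length, were chosen after seeing the data. The count of 0 genes in edgeR held for all comparisons under the size factors of DESeq2, without a filter, with limma in all its settings and, for each knockout against control, with only the 3 libraries compared. The Wald test of DESeq2 called 115 genes for sgPKA, 40 for sgALKBH5 and 309 between the knockouts, and moved PRKACA past the threshold at a log2 fold change of -2.784 (adjusted p 7.14e-11, and 0.226 to 0.666 in the other alternatives). In the self-test with uneven spread it also called 197 unchanged genes. There edgeR and limma recovered 0% of genes changed 4-fold or 16-fold, so their shared count of 0 cannot show that no gene changed. The number of genes at least 2-fold from both controls, 283 for sgPKA and 176 for sgALKBH5, became 605 and 288 with a pseudocount of 0.1, and 100 for sgALKBH5 with a mean TPM of at least 5. With 1 control left out it ranged from 668 to 1135 for sgPKA and from 301 to 974 for sgALKBH5, since passing against 1 control asks less than passing against both. Less the genes matched on GC content and length, the log2 fold change of PRKACA was -2.375 in sgPKA, and that of GPX4 was -0.347 in sgPKA and 0.262 in sgALKBH5. These subtract the median of 50 matched genes, while the median of -0.47 given for GPX4 elsewhere is that of 200. The correlation of changes was -0.566 with each knockout against its farther control and -0.0439 with each against its nearer control. The median of cAMP and CREB target genes in sgALKBH5 turned from 0.393 to -0.001 without control 2, and was 0.794 without control 1. The cause was not tested. Less matched genes, the sgPKA medians of the m6A and ferroptosis defence lists went from 0.224 to 0.042 and from 0.233 to 0.114. Other list medians kept their direction where they lay outside the middle 95% of random lists. Setting low counts to the floor of 3 moved list medians by up to 0.59.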

Other observations

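The test by expression level on chromosome 20 was chosen after its pattern had been seen. Genes of the cytokine and cytokine receptor pathway of KEGG made up 16 of the 69 annotated genes at least 2-fold above both controls in sgALKBH5, where 1.53 would fall by their share of all annotated genes. They included CD40, IL23A, CXCL11 and TNFRSF9. The same pathway also exceeded its share between the controls, with 21 of 272 annotated genes lower in control 2 (6.02 by share) and 7 of 86 higher (1.9 by share), and in sgPKA with 5 of 75 lower (1.66 by share), so this excess is not particular to sgALKBH5. Steroid biosynthesis made up 4 of the 47 annotated genes at least 2-fold above both controls in sgPKA, against 0.151, namely CYP51A1, MSMO1, SC5D and SQLE. The pathways were chosen after their counts were seen, among 313 pathways. Of genes at least 2-fold to the same side of both controls in both knockouts, SIPA1 was at 29.3 and 34.6 TPM in the controls, 13.6 TPM in sgPKA and 11.5 TPM in sgALKBH5. The complement gene C3 was at 5.54 and 7.13 TPM in the controls and at 23.6 and 18.5 TPM in the knockouts. These were also chosen after their values were seen.

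Some genes were expressed in one library and nearly absent in another. At least 10 TPM in control 1 and at most 3 counts in sgPKA were found for 35 genes, and the same from control 1 to control 2 for 9 genes. From control 2 there were 6 such genes to sgPKA, 4 to sgALKBH5 and 0 to control 1. From sgALKBH5 to sgPKA there were 47 such genes, and from sgALKBH5 to control 2 there were 16. From control 1 to sgALKBH5 there were 0.

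Control 1 lay closest to sgALKBH5, and control 2 was closer to sgPKA than to control 1. Library depth is argued against, since with every library thinned to the smallest total the standard deviation of log2 differences between the controls still exceeded that between control 1 and sgALKBH5 by 0.224 (0.623 and 0.399). GC content and transcript length explained 3.74% of the variance of the difference between the 2 pairs. The median of neighbouring genes in windows of 10 Mb explained 4.24%, above the highest of 20 shuffles at 0.0592%, so gains or losses of chromosome regions are not the main part of it. Separate rounds of culture or sequencing that paired each control with 1 knockout stay open, since the labels give none.

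GPX4 was lower in sgPKA than in both controls. A shared loss of selenoprotein transcripts is argued against for the 10 other selenoprotein genes measured, whose median log2 difference was 0.056. Selenoprotein genes that were not measured are not covered. The 10 genes went both ways, with 3 below both controls and 4 above both. GPX3 among them was at only 0.438 TPM in sgPKA, so its difference of 0.058 carries little weight. TXNRD2 was at -0.83, MSRB1 at -0.65 and SELENOI at 0.42. GC content and length may account for part of the difference: GPX4 lay at percentile 16.5 of the 200 genes closest to it in these, whose median was -0.47 against -0.91 for GPX4. These properties explained 6.63% of the variance of differences in sgPKA and 0.377% in sgALKBH5. The 169 other genes of the first 10 Mb of chromosome 19, where GPX4 lies, had medians of -0.34 and -0.46 in sgPKA against control 1 and control 2, and -0.08 less their matched genes. An effect of the guide on GPX4 beyond this stays open.

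On chromosome 20 both knockouts differed from the controls by segment, in opposite directions. Of 106 genes that start below 30 Mb, 91 lay below both controls in sgALKBH5, with medians of -0.69 and -0.67 against control 1 and control 2. Of 205 genes above 30 Mb, 177 lay above both controls, with medians of 0.29 and 0.49. In sgPKA the medians were 0.32 and 0.25 below 30 Mb, and -0.44 and -0.27 above it. Less genes matched on GC content and length, they were 0.26 and -0.25. Control 2 against control 1 gave -0.01 below 30 Mb and -0.20 above it, the latter in the direction of sgPKA. The 3 windows of 10 Mb below 30 Mb were among the 10 lowest of 297 in sgALKBH5. A candidate explanation is fewer copies of this segment in the sgALKBH5 cells, which would lower genes of any expression level alike. The 3 groups of genes by rising mean expression had medians of -0.685, -0.667 and -0.667, and the highest of them is -0.667. Since 91 of these 106 genes lay below both controls, a fall in every group was largely given beforehand. Only the like size of the fall across the groups adds to that. Above 30 Mb the 3 groups had medians of 0.45, 0.39 and 0.42. Shifts in sgALKBH5 were not confined to chromosome 20. On chromosome 22, 188 of 287 genes lay below both controls and 32 above both, with medians of -0.31 and -0.26 against control 1 and control 2. Copy number itself was not measured, and such a difference could arise from single-cell cloning or drift of the line as well as from the guides.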
